A study of Rattus norvegicus with 8 samples.

How the data were processed

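Polyadenylated RNA of rat hippocampal neuronal cultures was sequenced on an Illumina GAIIx in 4 libraries labelled vehicle and 4 labelled PAM, per the labels' protocols and design text. Total RNA was isolated with RNAiso Plus and libraries were built with the Vazyme VAHTS mRNA-seq V3 kit, per the labels' protocols. The authors deposited 1 table of whole-number gene counts per library, in the layout of featureCounts with Ensembl rat gene identifiers, exon coordinates and exonic lengths, per the file headers. STAR, featureCounts, DESeq2, DESeq and the genome build Rnor_6.0 are named per the submitters' processing notes, without versions. Annotation release, strandedness, the counting of reads or fragments, and the treatment of multi-mapped reads are not given in the sources used here. Genes with near-identical copies, such as ribosomal protein genes, and genes with overlapping or antisense partners therefore have uncertain values. Of the 185 genes selected for naming, 12 share exon bases with another annotated gene and 5 of those have a partner with counts.

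The authors also deposited a table of their own comparison, with group means (signal values), log2 fold changes, p-values and adjusted p-values, per the file headers; the table's name refers to DESeq2, and its version and design are not given in the sources used here. Its group means matched the deposited counts divided by median-of-ratios size factors within 0.175%, and 801 of its identifiers carry an adjusted p of 1. Gene symbols came from this table, which pairs 13739 Ensembl identifiers with symbols (368 repeated rows), with current symbols looked up in a RefSeq gene table of assembly GRCr8 used for names only. Of the tested genes 11329 had a symbol, and genes with a symbol held 97.6% of all counts. Coordinates are 1-based, on Rnor_6.0, and span the first to the last exon in the count tables. No genome sequence was used, so GC content was not checked.

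Libraries held 2960406 to 4389430 counts, and a count of 0 allows up to 0.684 to 1.01 CPM (3 counts of the total), a floor that covers counting error only. The 10 most abundant genes took 12.2% to 14.1% of counts and mitochondrial genes 11.8% to 14.1%. Replicates of a group differed by more than sampling noise (chi-square over degrees of freedom 2.77 to 14.8 over pairs), so none was treated as a duplicate. The labels give the replicates of both groups the same numbers without saying what a number marks.

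Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes passing filterByExpr (11740) were scaled by TMM and tested with the quasi-likelihood F test with robust dispersion, group as the only term, a Benjamini-Hochberg adjusted p under 0.05 and no fold threshold. Standard errors are the log2 fold change divided by the square root of F. The common biological coefficient of variation was 17.7% and the median SE of a log2 fold change 0.20. CPM values use TMM-scaled library sizes. The verbs rose, fell and changed are used for genes past this test.

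Before the data were examined, 34 gene lists (586 genes, 489 of them tested, 26 of these on more than 1 list) were fixed for neuronal activity, receptors, channels, synapses, stress, metabolism and cell types. Lists with at least 3 tested genes were tested with camera on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 33 lists. Intervals of medians are 95% bootstrap intervals over genes (10000 draws). Genes were named by a rule also fixed beforehand: the 12 largest increases and 12 largest decreases among symbol-bearing genes past the test with a mean of at least 1 CPM and groups that did not overlap, up to 4 members of each list with the smallest p, all NMDA receptor subunits, and Fos, Npas4, Arc, Bdnf and Nptx2. A further 28 genes were selected after their values were seen, to complete counts of 5 or fewer or to describe lists added later. Some of the selected genes are not reported here by name.

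Alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile scaling, no low-count filter, a minimum mean of 1 CPM in place of filterByExpr, a test against a 1.2-fold change, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. Removal of each library's trend with exonic length (loess, span 0.5) and leaving out both PAM 3 and PAM 4 were added after seeing the data.

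The procedure was tested on simulated counts drawn from the real means and library sizes for the PAM against vehicle comparison (11568 genes tested). It recovered 21.2% of 66 genes changed 1.5-fold, 72.7% of 66 changed 2-fold and 96.8% of 63 changed 4-fold, and 3 of its 126 calls (2.38%) were false. It called 5 of 5 shifted and 0 of 29 unshifted lists. The simulated genes varied independently, so this result does not cover lists of correlated genes. The length correction took a simulated slope from -0.147 to 0.00116. Most simulated changes of 1.5-fold were thus not detected at this depth and number of libraries. The simulation changed 200 genes, far fewer than the 2218 called in the real comparison, so recovery there may differ.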

Results

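Gene expression was measured by sequencing of polyadenylated RNA from wild-type rat (strain SD) hippocampal neuronal cultures on day 18 in vitro. In all, 4 libraries came from cultures given a positive allosteric modulator of the NMDA receptor (PAM), a compound class that strengthens the response of this glutamate-gated channel to its agonists, and 4 came from cultures given vehicle. The compound, its dose and the length of treatment are not given in the sources used here. Total gene counts were 3236761, 3679249, 3259506 and 3175404 in vehicle 1 to 4 and 4192778, 4389430, 3748263 and 2960406 in PAM 1 to 4. Of 32623 annotated genes, 19312 had a count in at least 1 library and 11740 were tested. Nothing in the labels says that the replicates are separate cultures. The p-values of single genes therefore measure the spread between these samples, which may be technical. Camera's p-values at the preset correlation rest on the spread between genes rather than between libraries. The comparison asks which transcripts differed in these cultures after potentiation of the NMDA receptor.

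PAM libraries had lower levels of synaptic and ion channel transcripts and higher levels of ependymal, oligodendrocyte, astrocyte and cell division markers than vehicle libraries. Of these lists, the sodium and calcium channel list alone also passed the set test (camera with Benjamini-Hochberg adjustment) at adjusted p = 0.0107 with an estimated correlation, and the others lay at adjusted p = 0.0849 to 0.3 with an estimated correlation. The chemokine gene Ccl2, which draws monocytes, rose from 35.6 ± 5.95 to 266 ± 28.2 CPM (counts scaled by library size; mean ± SD, n = 4 per group), a 7.48-fold difference. Neurod6, a transcription factor of excitatory forebrain neurons, fell from 94.7 ± 10.7 to 26.3 ± 4.78 CPM. The activity-regulated genes moved in both directions, with Fos at 60 ± 12.4 CPM in vehicle and 127 ± 19.5 CPM in PAM libraries, and Arc at 51.3 ± 11.5 and 18.2 ± 1.31 CPM. A total of 2218 genes changed (18.9% of those tested; edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 1057 of them higher and 1161 lower with PAM. Of these, 386 rose and 237 fell by more than 2-fold.

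By the rule for naming genes, the 12 largest increases were those of Crisp3, Hcrt, Fmo9, Ccl2, Armc3, Armh1, Adgb, Zbbx, Pifo, Dennd2c, Ibsp and Pde8a, with log2 fold changes from 3.74 ± 0.60 (SE) for Crisp3 to 2.53 ± 0.53 for Pde8a. Ccl2 (ENSRNOG00000007159; Rnor_6.0 chromosome 10, 69412017 to 69413870, plus strand) had the smallest adjusted p of all genes, 1.75e-10 by edgeR with Benjamini-Hochberg adjustment, at a log2 fold change of 2.90 ± 0.14. Most of the other increases started from very few counts: Hcrt, the orexin precursor gene (chromosome 10, 88669214 to 88670430), had 2 to 4 counts per vehicle library and 22 to 49 per PAM library, and Crisp3 had 0 to 4 and 23 to 41. The 12 largest decreases were those of Plxna4, Rem2, Mas1, Htr3a, Mtus2, Dgkg, Zcchc14, Cacng5, Hes5, Neurod6, Zbtb16 and Slc24a2, from -2.24 ± 0.40 for Plxna4 to -1.81 ± 0.30 for Slc24a2. Rem2, a small GTPase that restrains voltage-gated calcium channels, fell from 24.8 ± 4.76 to 5.16 ± 2.53 CPM, and Neurod6 (ENSRNOG00000026055; chromosome 4, 85911861 to 85915099, minus strand) fell by 1.83 ± 0.15 on the log2 scale. Among these 24 genes, 3 lost their call when 1 library was left out, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Htr3a lost its call without vehicle 4 (0.00855 to 0.0568) and Zcchc14 without vehicle 1 (0.00438 to 0.0543). Hes5 lost its call without vehicle 2, 3 or 4 or PAM 2 or 3 (0.0311 to 0.104). With PAM 3 and PAM 4 both left out, Hes5 (log2 fold change -1.49, adjusted p = 0.0858, range over 17 alternatives 0.0186 to 0.104) did not pass edgeR with Benjamini-Hochberg adjustment either. Every PAM library lay on the same side of every vehicle library for 22.3% of the tested genes, against 2.86% by chance.

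**Figure D1:**
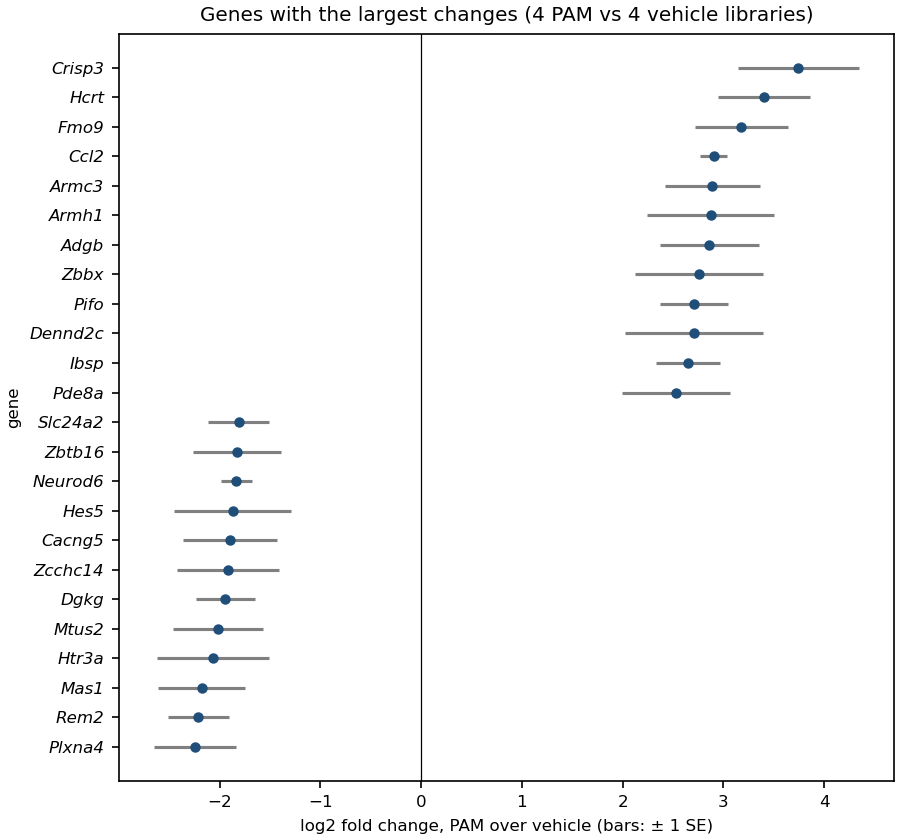
Log2 fold change (x axis, PAM over vehicle) of the 24 named genes with the largest changes (y axis). Points are edgeR estimates from 4 PAM and 4 vehicle libraries and bars are ± 1 SE; Crisp3 lies at 3.74 and Plxna4 at -2.24.

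The list of voltage-gated sodium and calcium channel genes includes auxiliary subunits, with Cacng2, Cacng3 and Cacng8 among them. Of its 25 tested genes, 16 fell (20 adjusted over the list alone) and 0 rose, with a median log2 fold change of -0.84. Scn2a fell by 1.17 ± 0.14, Cacnb3 by 0.84 ± 0.11, Cacna1h by 0.87 ± 0.16 and Cacna1a by 0.68 ± 0.12 on the log2 scale. This list passed the set test (camera, Benjamini-Hochberg adjusted p = 2.6e-11, and adjusted p = 0.0107 with an estimated correlation) and was the only one of the 15 lists past camera's test to hold with an estimated correlation. Voltage-gated potassium channel genes fell in 8 of 17 (9 adjusted over the list alone), among them Kcnq5 and Kcna6. The list had a median of -0.62 (camera, Benjamini-Hochberg adjusted p = 1.3e-05). This list lost its call, at adjusted p = 0.0849 with an estimated correlation. Of the presynaptic release machinery, 18 of 22 genes fell (19 adjusted over the list alone) and 1, the synaptotagmin gene Syt4, rose. The median was -0.60 (camera, Benjamini-Hochberg adjusted p = 1.82e-08). The list's call ended, at adjusted p = 0.0849 with an estimated correlation. The active-zone scaffold gene Bsn fell by 0.97 ± 0.11 on the log2 scale. Of the postsynaptic scaffold and signalling genes, 12 of 25 fell (17 adjusted over the list alone) and 0 rose. The list's median was -0.49 (camera, Benjamini-Hochberg adjusted p = 6.64e-07). The list did not pass, at adjusted p = 0.0869 with an estimated correlation. Shank1 fell from 226 ± 30.3 to 86.9 ± 11.9 CPM and Dlg4, which encodes the scaffold PSD-95, from 605 ± 62.7 to 386 ± 26 CPM. In the same libraries the median log2 fold change of the astrocyte markers was 0.40 and that of the ependymal and choroid plexus markers 1.88. Counts also fell with exonic length in PAM 3 and PAM 4 (slopes of -0.0853 and -0.132 log2 units per doubling of length, against 0.00524 to 0.0627 in the other 6 libraries); with that trend removed the medians were -0.70 for sodium and calcium channels, -0.53 for potassium channels, -0.56 for presynaptic and -0.38 for postsynaptic genes.

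Markers of excitatory neurons fell in 5 of 12 genes (8 adjusted over the list alone), Neurod6, Slc17a7, Neurod2, Neurod1 and Bcl11b, and rose in 1, the calmodulin-binding neurogranin gene Nrgn. Their median was -0.72 (camera, Benjamini-Hochberg adjusted p = 0.00454). This list lost its call, at adjusted p = 0.157 with an estimated correlation. Slc17a7, the vesicular glutamate transporter 1 gene, fell from 1234 ± 83 to 784 ± 75.7 CPM, whereas Nrgn rose from 169 ± 7.55 to 301 ± 81.9 CPM. Markers of inhibitory neurons fell in 4 of 13 genes (5 adjusted over the list alone), among them Slc32a1, Reln and Dlx1, and rose in 1, the parvalbumin gene Pvalb. The median was -0.49 (camera, Benjamini-Hochberg adjusted p = 0.0114). The list's call ended, at adjusted p = 0.21 with an estimated correlation. Without PAM 1 the median was -0.29 (camera, Benjamini-Hochberg adjusted p = 0.0402, range 0.000817 to 0.0402 over 15 alternatives). Slc32a1, the vesicular GABA transporter gene, fell by 0.94 ± 0.11 and Pvalb rose by 1.43 ± 0.23 on the log2 scale. Some neuron marker calls ended when 1 library was left out, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Neurod2 lost its call without vehicle 2 or 4 (0.0213 to 0.0813) and Neurod1 without vehicle 1, 3 or 4 or PAM 3 (0.017 to 0.071). Bcl11b lost its call without vehicle 2 or 3 or PAM 1 (0.0149 to 0.128) and Dlx1 without vehicle 1 or 4 or PAM 1 or 2 (0.00669 to 0.117). When PAM 3 and PAM 4 were both left out, Neurod1 (log2 fold change -0.91, adjusted p = 0.125, range over 17 alternatives 0.0137 to 0.125) did not pass edgeR with Benjamini-Hochberg adjustment, and the log2 fold change was 0.47 for Nrgn and -0.59 for Reln, against 0.83 and -1.03 with all libraries. Members named to complete counts of 5 or fewer, here and for the lists that follow, were chosen after their values were seen.

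Among NMDA receptor subunit genes, 3 of 5 tested changed (1 up and 2 down, the same numbers adjusted over the list alone). Grin2d fell from 36.7 ± 6.6 to 19.9 ± 3.75 CPM, Grin1, the obligatory subunit, from 751 ± 42.1 to 595 ± 74.4 CPM, and Grin2c rose from 16.2 ± 3.39 to 30.1 ± 4.92 CPM. Grin2a (log2 fold change -1.27 ± 0.71) and Grin2b (0.39 ± 0.35) did not pass, with groups that overlapped. Grin2a was at -2.13 without PAM 3, and Grin2b ran from 0.08 without PAM 4 to 0.69 without vehicle 3 and was at -0.32 without both PAM 3 and PAM 4. As a list the subunits had a median of -0.34 (camera, Benjamini-Hochberg adjusted p = 0.56), and of -0.22 with the length trend removed. The Grin1 call ended in some fits without 1 library, with the range of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Grin1 lost its call without vehicle 2, 3 or 4 or PAM 1 or 2 (0.0058 to 0.113). With the length trend removed its log2 fold change was -0.22 and it did not pass edgeR (Benjamini-Hochberg adjusted p = 0.19, range 3.22e-05 to 0.19 over 17 alternatives). Other receptor lists did not pass camera with Benjamini-Hochberg adjustment: AMPA and kainate subunits (median -0.38, adjusted p = 0.0846), metabotropic glutamate receptors (-0.46, adjusted p = 0.102) and GABA receptor subunits (-0.46, adjusted p = 0.0707). The metabotropic median was -0.83 without PAM 2, and the GABA receptor median was -0.29 without vehicle 3, without PAM 1 or without both PAM 3 and PAM 4. Within them Grik4, Gria1, Grik5 and Gria4 fell and Grik2 rose among 10 AMPA and kainate genes (1 up and 5 down adjusted over the list alone), Grm4 fell among 4 metabotropic receptor genes (1 adjusted over the list alone), and 4 of 13 GABA receptor genes fell, among them Gabbr2, Gabra5 and Gabbr1, and Gabrg1 rose (5 down and 2 up adjusted over the list alone). Gabbr2, a GABA-B receptor subunit gene, fell from 193 ± 6.53 to 76.5 ± 7.96 CPM. Calls of AMPA, kainate and GABA receptor genes also ended when 1 library was left out. Brackets hold ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits. Grik5 lost its call without vehicle 1, 2, 3 or 4 or PAM 1 or 2 (0.00768 to 0.121) and Gria4 without vehicle 1, 3 or 4 or PAM 1 or 3 (0.00123 to 0.12). Grik2 lost its call without vehicle 3 or PAM 2 (0.00664 to 0.076) and Gabbr1 without vehicle 2, 3 or 4 or PAM 1 (0.0144 to 0.0867). Gabrg1 lost its call without vehicle 2 or 3 or PAM 2 (0.0111 to 0.0809). With the length trend removed, Grik5 (log2 fold change -0.37, adjusted p = 0.122, range 1.69e-08 to 0.122) and Gabbr1 (log2 fold change -0.16, adjusted p = 0.292, range 0.00136 to 0.292) did not pass edgeR with Benjamini-Hochberg adjustment (ranges over 17 alternatives). Without both PAM 3 and PAM 4 neither did Gria4 (log2 fold change -0.45, edgeR, Benjamini-Hochberg adjusted p = 0.0975, range 0.00123 to 0.12), and the log2 fold change was -0.38 for Gria1 and -0.80 for Grik5, against -0.58 and -0.45 with all libraries. The AMPA and kainate list passed camera without PAM 2 and with no low-count filter (Benjamini-Hochberg adjusted p = 0.0477 and 0.0287, range 0.0287 to 0.203 over 15 alternatives). So did the GABA receptor list without PAM 2, without vehicle 2 and with no low-count filter (camera, Benjamini-Hochberg adjusted p = 0.0103, 0.0454 and 0.027, range 0.0103 to 0.232).

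Of 25 immediate early genes, the first transcripts induced by neuronal activity, 4 rose (Fos, Fosl2, Fosb and Nr4a2) and 3 fell (Arc, Egr1 and Nr4a1), against 5 and 4 adjusted over the list alone. The log2 fold change was 1.09 ± 0.15 for Fos (chromosome 6, 109300433 to 109303299) and -1.50 ± 0.19 for Arc (chromosome 7, 115907097 to 115910541), a regulator of AMPA receptor trafficking. Npas4 was at 44.1 ± 16.6 CPM in vehicle and 50.8 ± 7.24 CPM in PAM libraries and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.592). The list's median was 0.11, its mean -0.09 and its camera direction down (camera, Benjamini-Hochberg adjusted p = 0.97). Of 26 delayed activity-regulated genes, 8 rose and 3 fell (8 and 4 adjusted over the list alone), with a median of -0.02, a mean of 0.17 and an upward camera direction (camera, Benjamini-Hochberg adjusted p = 0.56). Plk2, a kinase, rose by 1.19 ± 0.12, the enkephalin precursor gene Penk by 1.16 ± 0.12 and Rgs2 by 1.47 ± 0.18 on the log2 scale. The 3 that fell were Dusp5, Dusp4 and Sorcs3. Bdnf, a neurotrophin gene, rose from 261 ± 54.3 to 354 ± 51.8 CPM with overlapping groups, and Nptx2 was at 369 ± 48.2 and 407 ± 22.4 CPM without passing. Several activity gene calls ended without 1 library, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Fosl2 lost its call without vehicle 1, 2 or 3 or PAM 2 or 3 (0.012 to 0.0783) and Fosb without vehicle 1 or 3 or PAM 3 (0.016 to 0.0743). Nr4a2 lost its call without vehicle 2 or 3 or PAM 1, 2 or 3 (0.017 to 0.132) and Nr4a1 without vehicle 2, 3 or 4 or PAM 1, 2 or 4 (0.0219 to 0.131). Sorcs3 lost its call without vehicle 1, 2, 3 or 4 or PAM 1, 3 or 4 (0.0109 to 0.131) and Bdnf without vehicle 1, 2 or 4 or PAM 3 or 4 (0.027 to 0.129). With the length trend removed, Fosl2 (log2 fold change 0.79, adjusted p = 0.0627, range 0.0112 to 0.0783) and Sorcs3 (log2 fold change -0.47, adjusted p = 0.0588, range 0.0109 to 0.215) did not pass edgeR with Benjamini-Hochberg adjustment (ranges over 17 alternatives). Without both PAM 3 and PAM 4 Bdnf (log2 fold change 0.35, edgeR, Benjamini-Hochberg adjusted p = 0.102, range 0.0025 to 0.129) did not pass, Sorcs3 was at -0.34 (adjusted p = 0.215), and Egr1 moved from -0.92 to -0.59. Upper-quartile scaling also ended the Sorcs3 call (edgeR, Benjamini-Hochberg adjusted p = 0.0591).

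**Figure D2:**
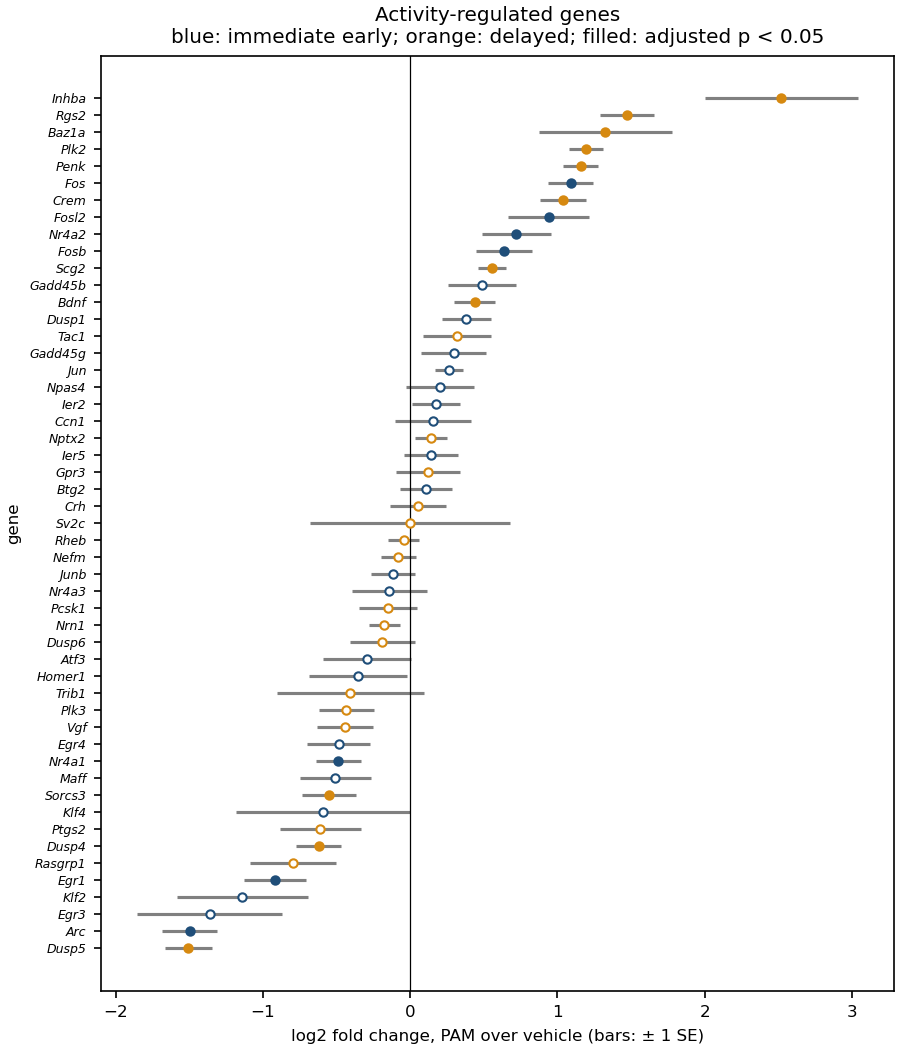
Log2 fold change (x axis, PAM over vehicle, 4 libraries each) of the genes on the immediate early (blue) and delayed (orange) activity lists (y axis). Bars are ± 1 SE and filled points passed edgeR's test at a Benjamini-Hochberg adjusted p under 0.05; Inhba lies at 2.52 and Dusp5 at -1.51.

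The MAPK phosphatases and Sprouty family, inhibitors of MAPK signalling, fell in 4 of 15 genes (5 adjusted over the list alone) and rose in 0. Their median was -0.46 (camera, Benjamini-Hochberg adjusted p = 0.135). Dusp5 fell from 77.9 ± 7.84 to 27.1 ± 5.13 CPM; the others were Dusp4, Spry4 and Spred2. Omission of 1 library ended calls on this list, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Spry4 lost its call without vehicle 4 (0.00288 to 0.0524) and Spred2 without vehicle 1, 3 or 4 (0.015 to 0.0932). Without both PAM 3 and PAM 4 the log2 fold change of Dusp4 was -0.37, against -0.62 with all libraries. The list's median was -0.25 without vehicle 3, -0.26 without PAM 4 and -0.14 without both PAM 3 and PAM 4. Without PAM 1 the list passed camera (Benjamini-Hochberg adjusted p = 0.0306, range 0.0306 to 0.443 over 15 alternatives). Of the 9 activity-regulated inhibitor of death genes, Serpinb2 and Inhba rose and Nr4a1 fell, the same numbers adjusted over the list alone. Their median was 0.20 (camera, Benjamini-Hochberg adjusted p = 0.161), and 0.13 without vehicle 1 or without PAM 1. Serpinb2, a protease inhibitor gene, rose from 7.44 ± 3.47 to 37.1 ± 5.47 CPM and Inhba, which encodes the activin A subunit, from 1.85 ± 1.59 to 10.7 ± 1.87 CPM. Of 20 neuropeptide and granin genes, Penk, Adcyap1, Scg2 and Scg3 rose and Chga and Chgb fell (4 and 3 adjusted over the list alone). Their median was -0.22 (camera, Benjamini-Hochberg adjusted p = 0.792), and -0.37 without both PAM 3 and PAM 4. Adcyap1, the PACAP precursor gene, rose from 163 ± 23.2 to 348 ± 28.8 CPM. Granin calls also ended without 1 library, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Scg3 lost its call without vehicle 1, 2, 3 or 4 or PAM 4 (0.0235 to 0.0995) and Chgb without vehicle 1, 2, 3 or 4 or PAM 1 or 3 (0.00517 to 0.0742). Among 10 neurotrophic factors and receptors, Bdnf rose and Vegfa fell (2 up and 1 down adjusted over the list alone). The median was 0.15, the mean -0.04 and the camera direction down (camera, Benjamini-Hochberg adjusted p = 0.974).

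Markers of non-neuronal cells rose in several lists. Of 10 listed ependymal and choroid plexus markers only 5 could be tested, and all 5 rose (5 adjusted over the list alone). The list had a median of 1.88 (camera, Benjamini-Hochberg adjusted p = 9.34e-06). The list did not pass, at adjusted p = 0.0849 with an estimated correlation. The 5 genes were Ccdc153, Dynlrb2, Rsph1, Folr1 and Tmem212, and Ccdc153 went from 14.5 ± 1.15 to 52.9 ± 16.4 CPM. Of the 5, only Folr1 also stood on the choroid plexus list added later. Ttr, Foxj1, Kcnj13, Aqp1 and Clic6 were listed but not tested. Proliferating cell markers rose in 13 of 16 genes (16 adjusted over the list alone) and fell in 0. The list's median was 0.94 (camera, Benjamini-Hochberg adjusted p = 1.4e-08). This list lost its call, at adjusted p = 0.107 with an estimated correlation. The mitotic kinase genes Aurkb and Cdk1 rose by 1.93 ± 0.26 and 1.00 ± 0.20 on the log2 scale, and Top2a by 0.87 ± 0.19. Astrocyte markers rose in 7 of 14 genes (7 adjusted over the list alone) and fell in 0. The list had a median of 0.40 (camera, Benjamini-Hochberg adjusted p = 8.1e-05). The list's call ended, at adjusted p = 0.21 with an estimated correlation. Gfap, the astrocyte intermediate filament gene, rose from 2807 ± 153 to 4622 ± 513 CPM and the gap junction gene Gja1 from 206 ± 11.9 to 394 ± 43.5 CPM. Oligodendrocyte markers rose in 5 of 7 genes (6 adjusted over the list alone), among them Cnp, Mbp, Ugt8 and Cldn11. The list's median was 1.52 (camera, Benjamini-Hochberg adjusted p = 0.00109). The list did not pass, at adjusted p = 0.3 with an estimated correlation. The myelin gene Mbp rose from 48.3 ± 3.98 to 192 ± 69.8 CPM.

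Among 8 oligodendrocyte precursor markers Olig1, Sox10 and Gpr17 rose and Pdgfra fell (4 and 1 adjusted over the list alone). Their median was 0.25 (camera, Benjamini-Hochberg adjusted p = 0.302). None of 6 microglia and macrophage markers passed edgeR with Benjamini-Hochberg adjustment (0 adjusted over the list alone, 1 at an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-voom); their median was -0.36 (camera, Benjamini-Hochberg adjusted p = 0.605), and -0.11 without vehicle 3, the vehicle library with the most C1qb, a member of the list. Of 7 mural cell and fibroblast markers, the collagen genes Col1a1 and Col3a1 rose (2 adjusted over the list alone). Their median was 0.04 (camera, Benjamini-Hochberg adjusted p = 0.696). Only 2 endothelial markers were tested, too few for the set test; Kdr rose (1 adjusted over the list alone) and Egfl7 had a log2 fold change of 0.09 ± 0.30, which ran from -0.08 without PAM 4 to 0.25 without PAM 2. Glial and endothelial calls ended when 1 library was left out, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Cldn11 lost its call without vehicle 1, 3 or 4 or PAM 1, 2 or 3 (0.00359 to 0.121) and Gpr17 without vehicle 1 or 2 or PAM 1 or 2 (0.012 to 0.0784). Pdgfra lost its call without vehicle 1 or 2 or PAM 1 or 3 (0.00253 to 0.0938) and Kdr without vehicle 2 or 3 or PAM 2 (0.0244 to 0.103). Without both PAM 3 and PAM 4, Col3a1 had a log2 fold change of 1.67 and did not pass edgeR's test (Benjamini-Hochberg adjusted p = 0.167, range 7.73e-07 to 0.167 over its 17 alternatives). In that fit Pdgfra (log2 fold change -0.32, edgeR, Benjamini-Hochberg adjusted p = 0.0917, range 0.00175 to 0.0938) did not pass either. The Cldn11 call ended with limma-voom (Benjamini-Hochberg adjusted p = 0.0635, range 0.00237 to 0.121 over 17 alternatives).

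**Figure D3:**
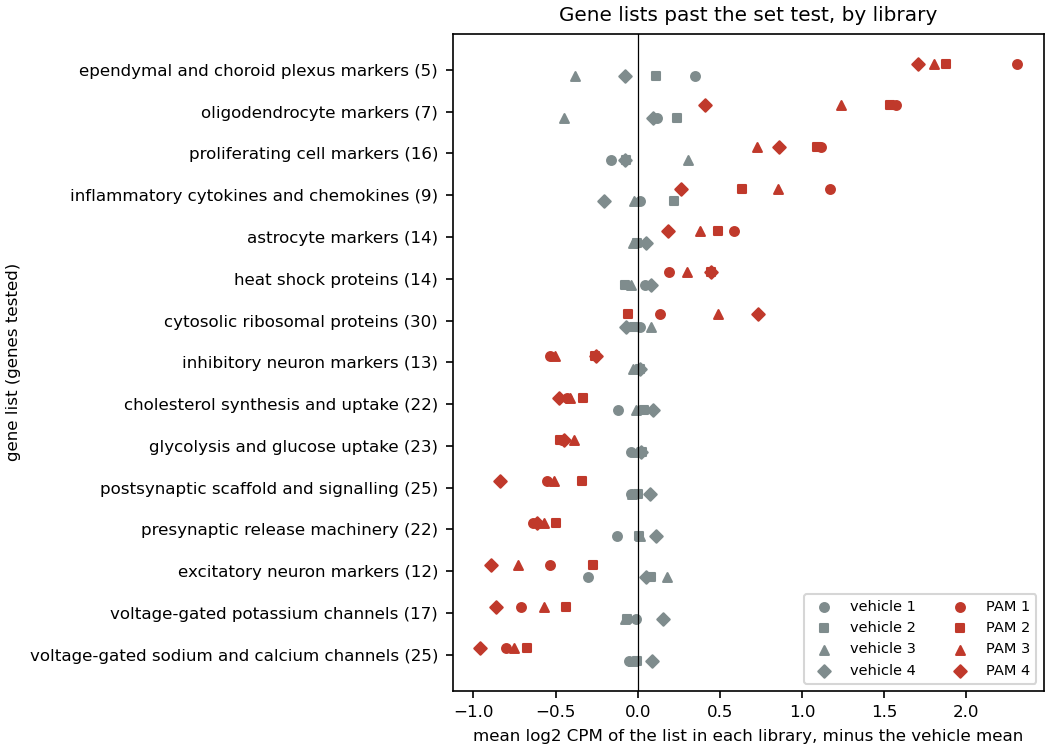
Mean log2 CPM of each gene list past camera's test in each library, minus the mean of the 4 vehicle libraries (x axis), with the number of tested genes in brackets (y axis). Grey symbols are vehicle and red symbols PAM libraries; in the sodium and calcium channel list the PAM libraries lie between -0.96 and -0.67, and ribosomal levels are -0.06 in PAM 2 and 0.73 in PAM 4.

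Glycolysis and glucose uptake genes fell in 12 of 23 (17 adjusted over the list alone) and rose in 1, the aldolase gene Aldoc, which is also an astrocyte marker. The median was -0.45 (camera, Benjamini-Hochberg adjusted p = 6.5e-06). This list lost its call, at adjusted p = 0.0849 with an estimated correlation. Hexokinase 2 (Hk2) fell from 92 ± 15.5 to 36.8 ± 3.98 CPM, Pdk1 from 118 ± 14.5 to 56.5 ± 6.51 CPM and Ldha from 2649 ± 107 to 1776 ± 84 CPM. Cholesterol synthesis and uptake genes fell in 13 of 22 (15 adjusted over the list alone) and rose in 0. The list had a median of -0.45 (camera, Benjamini-Hochberg adjusted p = 4.99e-06). The list's call ended, at adjusted p = 0.144 with an estimated correlation. The reductase gene Dhcr7 fell by 0.62 ± 0.11 on the log2 scale. In the same libraries the medians were -0.72 for excitatory neuron, -0.49 for inhibitory neuron and 0.40 for astrocyte markers. Nuclear genes of the mitochondrial respiratory chain showed 1 call among 36, an increase of Ndufa5 (1 adjusted over the list alone), and a median of 0.05 (camera, Benjamini-Hochberg adjusted p = 0.696). Without both PAM 3 and PAM 4 that median was -0.13 and the list passed (camera, Benjamini-Hochberg adjusted p = 0.0266, range 0.0266 to 0.962 over 15 alternatives). Ndufa5 had a log2 fold change of 0.67, which was 0.44 with the length trend removed and 0.40 without both PAM 3 and PAM 4.

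Cytosolic ribosomal protein genes rose in 6 of 30 (10 adjusted over the list alone). The list's median was 0.35 (camera, Benjamini-Hochberg adjusted p = 0.000175). The list did not pass, at adjusted p = 0.535 with an estimated correlation. The list mean differed between PAM libraries, from -0.06 in PAM 2 and 0.13 in PAM 1 to 0.49 in PAM 3 and 0.73 in PAM 4, relative to the vehicle mean. The median was 0.20 without PAM 4, 0.19 with the length trend removed and 0.02 without both PAM 3 and PAM 4, where the list did not pass (camera, Benjamini-Hochberg adjusted p = 0.616, range 1.16e-07 to 0.616 over 15 alternatives). The list also did not pass fry (Benjamini-Hochberg adjusted p = 0.163). Of the 4 genes with the smallest p, Rps23 and Rps16 lost their call without any 1 of the vehicle libraries, PAM 3 or PAM 4 (Benjamini-Hochberg adjusted p over the 8 edgeR fits 0.00281 to 0.0958 and 0.00161 to 0.16). Rpl14 and Rpl5 lost theirs without vehicle 2 or 4 (edgeR, Benjamini-Hochberg adjusted p 0.000572 to 0.0606 and 0.00483 to 0.0741). Rps23 and Rps16 also did not pass limma-voom (Benjamini-Hochberg adjusted p = 0.0525 and 0.0723) or edgeR without both PAM 3 and PAM 4 (adjusted p = 0.127 and 0.513), nor Rps23 with the length trend removed (adjusted p = 0.0904), with ranges over 17 alternatives of 0.000431 to 0.127 for Rps23 and 0.00161 to 0.513 for Rps16. Without both PAM 3 and PAM 4 the log2 fold change was 0.20 for Rps23, 0.09 for Rps16, 0.26 for Rpl14 and 0.25 for Rpl5, against 0.50, 0.42, 0.49 and 0.44 with all libraries. Ribosomal protein genes have many near-identical pseudogenes, so their single-gene values are uncertain. Heat shock genes rose in 3 of 14 (3 adjusted over the list alone), Bag3, Hspb1 and Hspe1. The list had a median of 0.24 (camera, Benjamini-Hochberg adjusted p = 0.0167). This list lost its call, at adjusted p = 0.326 with an estimated correlation. The co-chaperone gene Bag3 rose from 34.3 ± 4.48 to 84.7 ± 6.56 CPM; the list's call ended without PAM 2 (median 0.17; camera, Benjamini-Hochberg adjusted p = 0.0535, range 0.00346 to 0.0535 over 15 alternatives). Of 20 unfolded protein and integrated stress response genes, Sesn2 rose and Hyou1 and Trib3 fell (1 and 2 adjusted over the list alone), with a median of 0.02, a mean of -0.00056 and an upward camera direction (camera, Benjamini-Hochberg adjusted p = 0.908). Of 16 pro-apoptotic and p53 target genes, Bcl2l11 and Txnip rose (1 adjusted over the list alone). Their median was 0.08 (camera, Benjamini-Hochberg adjusted p = 0.489), and 0.13 without vehicle 2, 0.12 without PAM 2 and 0.11 without PAM 3. Stress gene calls ended too when 1 library was removed, with ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits in brackets. Hspe1 lost its call without vehicle 1, 2, 3 or 4 or PAM 4 (0.022 to 0.068) and Bcl2l11 without vehicle 1 or 3 or PAM 2 or 3 (0.00161 to 0.0621). Txnip lost its call without vehicle 1, 2, 3 or 4 or PAM 1 or 2 (0.00417 to 0.172). With the length trend removed Hspe1 (log2 fold change 0.14, adjusted p = 0.456, range over 17 alternatives 0.0141 to 0.456) did not pass edgeR with Benjamini-Hochberg adjustment, against a log2 fold change of 0.37 without that step, nor did it pass without both PAM 3 and PAM 4 (adjusted p = 0.0559). The Txnip call ended with limma-voom (Benjamini-Hochberg adjusted p = 0.058, range 7.82e-06 to 0.172 over 17 alternatives), and without both PAM 3 and PAM 4 its log2 fold change was 0.76, against 0.48.

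The inflammatory cytokine and chemokine list also holds other inflammatory genes, and 9 of its 18 genes could be tested. Of these 9, 5 rose (6 adjusted over the list alone), the chemokine genes Ccl2 and Ccl7 and also Serpina3n, Vcam1 and Nfkbia. The lipocalin gene Lcn2 fell. The median was 0.64, with an interval of -0.76 to 2.53 that includes 0 (camera, Benjamini-Hochberg adjusted p = 0.00876). The list's call ended, at adjusted p = 0.266 with an estimated correlation. Ccl7, which lies beside Ccl2 on chromosome 10 (69423086 to 69424979), rose from 10 ± 2.33 to 57.9 ± 13.1 CPM, and Lcn2 fell from 314 ± 45.3 to 140 ± 36.4 CPM. Of 12 interferon response genes Mx2, Ifi27 and Psmb9 rose and Mx1 fell (3 and 1 adjusted over the list alone), with a median of 0.36 (camera, Benjamini-Hochberg adjusted p = 0.0939); Mx1 and Mx2 are paralogs. On the perineuronal net and matrix proteoglycan list 4 of 17 genes rose (5 adjusted over the list alone), Timp1, Adamts4, Tnc and Bcan. Only Bcan among these encodes a proteoglycan. Their median was 0.33 (camera, Benjamini-Hochberg adjusted p = 0.0846). The aggrecanase gene Adamts4 rose from 2.81 ± 0.306 to 11.9 ± 2.83 CPM. Calls of inflammatory, interferon and matrix genes ended when 1 library was left out. Brackets hold ranges of the Benjamini-Hochberg adjusted p over the 8 edgeR fits. Nfkbia lost its call without vehicle 2, 3 or 4 or PAM 1 (0.0137 to 0.0778) and Ifi27 without vehicle 2 or 4 (0.00313 to 0.0674). Psmb9 lost its call without vehicle 1 or 4 or PAM 4 (0.0183 to 0.0772) and Mx1 without vehicle 3 or 4 or PAM 1 or 2 (0.00363 to 0.0908). Tnc lost its call without vehicle 2, 3 or 4 or PAM 1 (0.0139 to 0.131) and Bcan without vehicle 1, 2, 3 or 4 or PAM 1, 2 or 3 (0.00209 to 0.147). With PAM 3 and PAM 4 both left out, Psmb9 (log2 fold change 0.57, adjusted p = 0.11, range 0.015 to 0.11) and Ifi27 (log2 fold change 0.47, adjusted p = 0.0555, range 0.00275 to 0.0674) did not pass edgeR with Benjamini-Hochberg adjustment (ranges over 17 alternatives). Bcan did not pass limma-voom or edgeR with a minimum mean of 1 CPM (Benjamini-Hochberg adjusted p = 0.0533 and 0.0551, range 1.09e-05 to 0.147 over 17 alternatives), and its log2 fold change was 0.51 without both PAM 3 and PAM 4, against 0.33. The interferon median was 0.22 without PAM 1, and the matrix median was 0.18 without PAM 2. The matrix list passed camera without PAM 3, PAM 4 or both and with the length trend removed (Benjamini-Hochberg adjusted p = 0.0487, 0.0301, 0.00377 and 0.0116, range 0.00377 to 0.281 over 15 alternatives), and the interferon list without both PAM 3 and PAM 4 (adjusted p = 0.0256, range 0.0256 to 0.215).

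In total 15 of 33 tested lists passed camera at the preset correlation, 7 upward and 8 downward. With an estimated correlation 1 of them passed, the sodium and calcium channel list. The mean levels of the PAM libraries lay wholly above the vehicle libraries for 10 of the 33 lists and wholly below for 8, where chance gives 0.943 in total; among the lists past the test, the excitatory and ribosomal lists overlapped. The estimated correlation between a list's genes ran from -0.0423 for metabotropic receptors to 0.81 for ribosomal proteins, against the preset 0.01. Of the 35 splits of the 8 libraries into equal groups, 4, the real one included, called at least 15 lists.

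The authors' deposited table of PAM against vehicle lists 13739 gene identifiers, of which 2392 have an adjusted p under 0.05 (1159 higher and 1233 lower with PAM). Of these 2392, 2313 were tested here with edgeR and 2168 passed here too, all 2168 in the same direction as in the authors' deposited table. Of the edgeR calls, 2173 have an identifier in the authors' deposited table and 5 of those were called here alone. Both sets of calls come from the same 8 libraries, so their overlap is no independent evidence.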

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

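The tests of the cell-type shifts as one neuron loss, of an equal loss for all neuronal genes and of the activity gene lists were chosen only after results were seen, and the length correction is an added alternative; the other tests were chosen before their results.

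Libraries far from the other 3 of their group were sought by Dixon's test in 458 groups of 4; chance flags about 1 in 20 groups (22.9 here), and 12 were found. The total count of vehicle 2 was 3679249, against 3175404 to 3259506 in the other vehicle libraries. The level of the NMDA receptor list was 0.18 in PAM 3, against -0.47 to -0.37 in the other PAM libraries. Among PAM libraries, PAM 1 stood apart at 7.14 CPM for Armh1 (others 3.61 to 3.84) and at 34.1 CPM for Calml4 (24.9 to 25.2), and PAM 2 at 1876 CPM for Scg2 (1521 to 1579). PAM 3 had 441 CPM of Nptx2 (394 to 398), and PAM 4 had 22.7 CPM of Nefh (16.4 in the others) and 19.5 CPM of Dusp5 (29.3 to 30.2). Among vehicle libraries, vehicle 1 had 124 CPM of Ntsr2 (147 to 149), vehicle 3 had 3.76 CPM of Rsph1 (9.45 to 9.91) and 18.5 CPM of C1qb (8.09 to 9.15), and vehicle 4 had 8.09 CPM of Grm7 (10.7 to 11.3).

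The real split of the 8 libraries into equal groups called 2218 genes. EdgeR with Benjamini-Hochberg adjustment called 0 in each of the other splits, all of which mixed the groups (66 to 1292 at an unadjusted p under 0.05, against 3740, and no other tool was run on the splits). No other division of these libraries thus reached the gene count, and 1 of 35 is the smallest share that this test can give. It cannot exclude a difference between cultures that arose without PAM, since the replicates may not be separate cultures. For the 15 lists a chance division cannot be excluded by count alone: 4 of 35 splits called as many, the highest other 16. The 3 others that did so were among the 16 splits that exchange 1 library between the groups, which called 7 to 16 lists, whereas the 18 balanced splits called 0 to 3.

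The 89 tested genes of the sodium and calcium channel, potassium channel, presynaptic and postsynaptic lists had a median log2 fold change of -0.65, with 54 lower and 1 higher. Neither the length trend (median -0.55, interval -0.62 to -0.49, with it removed) nor PAM 4 (median -0.62 without it) accounts for this. A lower share of neurons as the one source of all cell-type shifts would raise other cell types alike, but 3 of 6 pairs among the astrocyte, ependymal, mural and microglia medians had intervals that did not overlap, all 3 involving the ependymal and choroid plexus list, and the oligodendrocyte median (1.52, interval 0.94 to 2) also lay clear of the astrocyte (0.27 to 0.68) and microglia (-0.81 to 0.42) intervals, so what stays open is a neuron loss beside separate changes of these types. A loss by 1 factor for all members predicts little relation between separate sets of libraries. The members' fold changes in replicates 1 and 2 correlated with those in replicates 3 and 4 (r = 0.439, rho = 0.439 across 89 genes, which are not independent replicates, permutation p = 4e-05, two-sided). These fold changes used log2 CPM with a prior count of 2, which shrinks members of low count alike in both sets. Its share in r was not tested, so the correlation does not exclude a loss by 1 factor. The pan-neuronal markers' median lay 0.40 above that of the members (interval -0.08 to 0.51, including 0). A partial loss of neurons, diluted where other cells express the same genes, together with changes within neurons may account for the pattern; the tables do not separate these.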

How the results depend on the processing

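The length correction and the fits without both PAM 3 and PAM 4 were chosen after seeing the data. The number of changed genes stayed within 1.5 times of 2218 with DESeq2, limma-voom, both other scalings, both other filters, the block, the length correction and without both PAM 3 and PAM 4 (2064 to 2900). Against a 1.2-fold change it was 1179 (577 higher, 602 lower), since that test asks for a larger effect. With each library left out in turn it was 1527 to 2408 (713 to 1148 higher, 796 to 1269 lower), the lists 15 to 16, and the calls shared with the list the authors deposited were 1479 to 2024. Of the 2218 calls, these fits kept 67.2% (without vehicle 4) to 90.1% (without PAM 4). A gene's lost call in such a fit therefore does not single out the library left out. With an estimated correlation 1 list passed camera. That sodium and calcium channel list had an estimate of 0.00756, below the preset 0.01. Its adjusted p (camera, Benjamini-Hochberg) still went from 2.6e-11 to 0.0107. Larger correlations are thus not the only cause: with an estimated correlation, camera also takes its degrees of freedom from the libraries. With fry, which asks only whether a list's genes move one way on balance and sets them against no other genes, 21 lists passed, which added the AMPA and kainate, metabotropic, GABA receptor, inhibitor of death, oligodendrocyte precursor, interferon and matrix lists and left out the ribosomal list. At an adjusted p under 0.01 in both sets 1147 calls were shared with the authors' deposited table. The mitochondrial respiratory chain list reversed, to a median of -0.13 without both PAM 3 and PAM 4; the cause was not tested. Medians near 0 of lists that did not pass changed sign when 1 library was left out: immediate early genes to -0.03 without vehicle 1 and -0.07 without PAM 1, delayed genes to 0.03 without vehicle 2 and 0.05 without PAM 3, neurotrophic factors to -0.01 without PAM 3, mural markers to -0.06 without vehicle 2, -0.21 without PAM 1 and -0.00031 without PAM 2, and the mitochondrial list to -0.01 without PAM 4. The unfolded protein median ran from 0.00089 without PAM 2 to 0.08 without PAM 4. Same-numbered libraries did not deviate together (correlations -0.0595 to 0.0675, and 2 of 8 matched their own number best). With 4 libraries per group this check cannot exclude that a number marks a shared preparation. With the replicate number as a block 2064 genes and 15 lists passed, and 1969 of the 2218 calls were kept. Hes5, Nr4a2, Nr4a1, Scg3 and Bcan did not pass with the block. Of the 185 genes selected for naming, 157 had a call, and none of these changed direction over 17 alternatives. Some genes without a call did change direction, among them Grin2b, Egfl7 and Igfbp2. Of 3143 values 2920 kept their side of the threshold, 207 lost it and 16 gained it. The call was never lost for 113 of the 157 genes, and for the 24 largest changes 399 of 408 values were kept. At this depth (2960406 to 4389430 counts), with 4 libraries per group and 200 changed genes, the simulated test recovered 21.2% of changes of 1.5-fold. No other depth or number of changed genes was simulated.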

Other observations

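The lists of cilia, choroid plexus, pan-neuronal, cAMP/CREB-type and ERK/SRF-type genes were composed after results had been seen, so the list tests here were chosen afterwards; the length correction is an added alternative, and the tests on length, single libraries and choroid plexus were set before their values were seen.

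Genes of motile cilia, the beating structures of ependymal cells, rose together in the PAM libraries: 58 of 70 tested rose (61 adjusted over the list alone) and 0 fell, with a median log2 fold change of 1.42 (camera, Benjamini-Hochberg adjusted p = 1.93e-27 over the 5 added lists, but adjusted p = 0.0574 with an estimated correlation). Cfap126 rose from 15.6 ± 3.38 to 54.8 ± 11.2 CPM (mean ± SD, n = 4), Fam216b from 3.89 ± 1.19 to 22.3 ± 4.83 CPM and Rsph10b from 16 ± 2.91 to 49.4 ± 10.9 CPM. The median of the genes' mean levels was 6.5 CPM in vehicle and 17.3 CPM in PAM libraries, and 69 of 70 had at least 1 CPM in vehicle libraries, so cilia transcripts were present without PAM. Before the list was composed, 12 members had been seen among the largest changes or stood on the ependymal list; the other 58 had a median of 1.30, with 46 higher and 0 lower. Of 17 pan-neuronal markers, 6 fell (7 adjusted over the list alone), with a median of -0.25 (camera, Benjamini-Hochberg adjusted p = 0.000153, but adjusted p = 0.0624 with an estimated correlation): Tubb3 fell from 668 ± 92.8 to 375 ± 56.5 CPM, whereas Map2 was at 590 ± 33.3 and 529 ± 51.4 CPM and Nefl at 670 ± 43.4 and 680 ± 82.2 CPM.

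The cilia pattern did not rest on gene length (median 1.41 with the trend removed) or on 1 library (lowest median 1.31 when each was left out, and the lowest PAM library 0.73 above the highest vehicle library in mean level). Choroid plexus epithelium, a candidate source of such transcripts, cannot be told apart by the test used. Its list had a median of 1.41 over 6 tested genes with an interval of 0.07 to 1.98 (camera, Benjamini-Hochberg adjusted p = 0.000849, but adjusted p = 0.0574 with an estimated correlation). Of them 4 were higher, Folr1, Calml4, Lmx1a and Enpp2 (4 adjusted over the list alone). The rule set for this list also asked for a rise of its abundant gene Ttr. Ttr was not found by symbol among the tested genes, so that rule could not be met. Kcne2, another member, was at 5.39 ± 2.43 and 5.29 ± 1.18 CPM and did not pass (edgeR, Benjamini-Hochberg adjusted p = 0.957). Igfbp2, the most abundant member, was at 1546 ± 108 CPM in vehicle and 1767 ± 402 CPM in PAM libraries and did not pass, except without PAM 2 (edgeR, Benjamini-Hochberg adjusted p = 0.0358, range 0.0358 to 0.758 over the 8 fits without 1 library each), and its log2 fold change was -0.07 without both PAM 3 and PAM 4. As a hypothesis, PAM cultures may hold more ciliated cells or more cilia transcripts per cell; the design gives no cell counts to separate these.

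The activity genes that rose and those that fell may belong to different pathways. Of the cAMP/CREB-type genes 13 of 26 rose and 2 fell (16 and 3 adjusted over the list alone; median 0.56), and of the ERK/SRF-type genes 7 of 19 fell and 0 rose (10 and 0 adjusted over the list alone; median -0.52); both passed camera (Benjamini-Hochberg adjusted p = 0.000153), but not with an estimated correlation (adjusted p = 0.12 with an estimated correlation for each). Because most members' values were known when the lists were composed, the difference was tested on the 9 and 10 members on neither activity list, some of which stand on other lists whose counts had been seen: their means differed by 0.58 (exact permutation p = 0.0384, two-sided, 92380 reassignments). That p treats genes as independent, whereas the estimated correlation was 0.15 within the whole cAMP/CREB-type list and 0.241 within the ERK/SRF-type list. With the length trend removed the difference of all members' means stayed at 1.09, so length bias does not account for it. The libraries hold no measure of either pathway, so whether the pathways themselves differ was not tested.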
